A study of Rattus norvegicus with 4 samples.

How the data were processed

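Single-cell RNA sequencing was carried out on dorsal root ganglia (DRG), the clusters of sensory neuron cell bodies beside the spinal cord, from male Sprague-Dawley rats. Per the labels, ipsilateral L4-L6 ganglia of sham rats and of rats of the CPIP model were dissociated with dispase, collagenase and papain, and tissue of 3 rats was pooled for each library. Cells were captured in microwells with barcoded beads (BD Rhapsody whole transcriptome), so that each cDNA carried a cell barcode and a unique molecular identifier (UMI). The labels give 4 libraries, named Sham 1, Sham 2, CPIP 1 and CPIP 2, as 2 biological replicates per group. The labels use CPIP without spelling it out; in the field it stands for chronic post-ischaemia pain.

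The deposited values were raw UMI counts per gene and cell barcode, with no normalization, per the file headers and the whole-number values. The aligner, the annotation, the genome build and the rule that called cells are not given in the sources used here. No barcode held fewer than 500 UMIs, which was found in the values and is not stated. All 4 libraries listed the same 25629 features, of which 3852 had no gene symbol and 431 symbols were shared by several features, and no coordinates are given because the build is not known. UMIs of near-identical copies of a gene may have been split by the counting, and strand was not described.

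Cells with under 200 genes or over 25% mitochondrial UMIs were removed, which left 11306, 11229, 12175 and 11969 cells in Sham 1, Sham 2, CPIP 1 and CPIP 2. Doublets were called per library with scrublet as run in scanpy 1.11.5 (expected rate 0.05), which marked 206, 171, 2 and 255 cells. In CPIP 1 the caller marked under 0.5% of the cells and was taken to have failed, so the 5% of its cells with the highest doublet scores, 609 cells, were removed instead. Counts were scaled to 10000 per cell and log-transformed. Clustering used 2000 variable genes, 30 principal components, 15 neighbours and the Leiden method at resolution 1.0, without batch integration (Python 3.11.15, anndata 0.12.19, igraph 0.11.9, scikit-learn 1.9.0, scipy 1.17.1, numpy 2.4.6, pandas 2.3.3).

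Clusters were named from marker lists fixed before the data were examined, of which 313 of 330 symbols were in the files. A class name therefore means likeness to that class in these markers. A cluster needed at least 3 detected markers, and no more markers of another class than of its own among its 10 leading genes. The margin between the best and the next class, the detection minimum of 10% of cells, and the handling of low-UMI clusters were set after the clusters had been seen. Clusters with a median UMI count under that of their libraries divided by 3 were kept apart as low-UMI clusters where fewer than 3 of their own markers led them; pericytes (median 1056 UMIs) had 3 and kept their name. The low-UMI clusters held 11.4% of the retained cells in Sham 1, 16.4% in Sham 2, 18.0% in CPIP 1 and 14.1% in CPIP 2. A cluster of mixed leukocyte genes stayed unnamed. Neurons and macrophages were re-clustered alone at resolution 0.5. Where the doublets were kept or the cells were filtered differently, class names were carried over from the retained cells, a choice made after the data had been seen.

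UMI counts were summed per library and class, since libraries and not cells are the replicates, and the sums were compared as 2 CPIP against 2 Sham libraries. The test was the quasi-likelihood test of edgeR 4.0.16 (R 4.3.3) with TMM normalization, the default low-count filter and Benjamini-Hochberg adjustment within a class, and genes with adjusted p under 0.05 were called. Classes with full accounts were the 5 with the most cells, each with at least 100 cells in every library, plus macrophages; 4 other classes with at least 30 cells in every library were tested for counts of calls. Fold changes are log2 of CPIP over Sham with the standard error of the fit, and levels are CPM, counts scaled to the total UMIs of the tested genes of the class times the TMM factor, with the SD over 2 libraries; the plot and the ratios of Rpl10a-ps9 are without the TMM factor. A total of 28 gene lists fixed before the data were examined (683 of their 716 symbols were in the files) was tested with camera in limma 3.58.1 at a preset correlation of 0.01, for lists with at least 5 tested members, with Benjamini-Hochberg adjustment over 156 tests of list and class. The same lists were tested with an estimated correlation and with fry. Marker lists and lists of ribosomal protein and mitochondrial genes were tested the same way, each kind adjusted on its own. Shares of cells were compared with a two-sided exact permutation test, whose smallest possible p with 2 against 2 libraries is 0.33.

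Named genes followed a rule fixed before the data were examined. Per class these were the 10 largest rises and the 10 largest falls among called genes with a mean of at least 32 CPM and both CPIP libraries on the same side of both Sham libraries. Where fewer than 5 genes passed, the 5 with the smallest p are named as not past the test, and up to 4 members with the smallest p are named for each called list. Symbols that are only clone or locus names, and haemoglobin genes, were skipped; this passed over 3 features in satellite glia and 1 in neurons. Rpl10a-ps9 lies below the CPM minimum of the rule for called genes and was singled out after its values were seen, as were B3galt4, Rpl28, Eef1a1 and the genes of the sub-cluster led by Vip.

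The whole test was checked on simulated counts drawn from the real means and library sizes, with 200 changed genes per draw and 3 draws per class. With the spread taken from the fitted trend, false calls made up 3.7% of calls in satellite glia and 6.5% in neurons; with the spread of each gene they made up 16.3% and 12.7%, above the nominal level. With the trend, genes changed 4-fold were recovered at 96.4% in neurons and 88.5% in macrophages, and genes changed 2-fold at 64.8% and 26.8%. The simulated genes varied independently, no library was shifted as a whole, and 200 true changes ease the adjusted threshold. These rates may therefore be too high for the data. Rpl10a-ps9 in satellite glia, for one, did not pass (log2 fold change 5.35, edgeR adjusted p = 0.314). Options of the edgeR fit were compared on simulated counts only.

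Alternatives fixed before the data were examined were the size factors and the Wald test of DESeq2 1.42.0, no low-count filter, the replicate number as a block, each library left out in turn, doublets kept, a stricter cell filter (500 genes, 10% mitochondrial UMIs), Leiden resolution 2.0, equal cell numbers per library, an edgeR test of cell counts, the other set tests, and sub-clusters at resolution 1.0. Chosen after seeing the data were a crossed pairing, the highest 5% of doublet scores removed in every library, mixed sub-clusters left out, neurons joined with low-UMI clusters that resemble them, neurons without the Vip sub-cluster, limma on log CPM, and comparisons of a class with the other classes or with all other tested cells of its library. With 1 library left out, the lone library of its group was assumed to vary like the other group. Groups of 2 libraries allow few other splits of the samples, and genes were not called under them. Replicate libraries differed by more than sampling noise, with a chi-square per degree of freedom of 10.2 for the Sham pair and 29.0 for the CPIP pair in satellite glia, so each counted as 1 replicate. No library was left out of the main comparison. Results of some single genes are not reported here. Figures were drawn with matplotlib 3.10.9.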

Results

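The data comprised 4 libraries of dissociated L4-L6 ganglion cells, 2 from sham rats and 2 from rats of the CPIP model, each a pool of 3 rats. The libraries held 11829 (Sham 1), 11860 (Sham 2), 12828 (CPIP 1) and 12651 (CPIP 2) cell barcodes. Their totals were 60885664, 64550637, 62358475 and 63541024 UMIs in the same order. Median UMIs per barcode were 3976, 4141.5, 3531 and 3707, and median mitochondrial shares were 10.7%, 11.0%, 10.2% and 10.4%. After filtering, 11100, 11058, 11566 and 11714 cells were retained. The question the series sets is how the cells of the ganglia differ between the sham and the CPIP group.

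Satellite glia, the cells that wrap sensory neuron bodies, were the most numerous class, followed by neurons. This order depended on the cell filter. Under the strict filter 384, 238, 306 and 362 satellite glia were left in Sham 1, Sham 2, CPIP 1 and CPIP 2. Neurons then numbered 2564, 2389, 2294 and 2074 and were the largest class. The gene lists were not tested under that filter. Satellite glia made up 36.8% ± 0.928 (SD, n = 2 libraries) of the retained cells in Sham and 35.8% ± 2.99 in CPIP. Neurons made up 26.1% ± 1.67 in Sham and 21.2% ± 1.70 in CPIP, and endothelial cells 7.62% ± 0.0843 and 6.08% ± 0.201. Macrophages made up 1.61% ± 0.340 in Sham and 2.79% ± 0.771 in CPIP. Fibroblasts held 1.20% ± 0.558 and 3.03% ± 1.87, and myelinating Schwann cells 2.96% ± 1.11 and 4.53% ± 0.0382. Non-myelinating Schwann cells, which ensheathe small axons, held 5.6% ± 0.649 in Sham and 6.69% ± 1.22 in CPIP. Smooth muscle cells held 1.91% ± 0.00513 in Sham and 1.20% ± 0.184 in CPIP. For neurons, endothelial cells, macrophages, fibroblasts, myelinating Schwann cells and smooth muscle cells both CPIP libraries lay on the same side of both Sham libraries. This gave an exact permutation p of 0.33 (adjusted p = 0.481), the smallest p this design allows. No class share could therefore pass this permutation test. Joined with the low-UMI clusters that resemble them, neurons held 37.8% and 40.0% of cells in Sham 1 and Sham 2 and 38.9% and 32.6% in CPIP 1 and CPIP 2. CPIP 1 then lay between the Sham libraries, and the log2 ratio of −0.30 became −0.12. The log2 share ratio of myelinating Schwann cells, 0.62, was 1.06 without Sham 1 and 0.28 without Sham 2. That of fibroblasts, 1.34, was 0.51 without CPIP 2, whose share was 4.35%, and that of macrophages, 0.80, was 0.49 without CPIP 2. The ratio of non-myelinating Schwann cells, 0.25, was 0.06 without CPIP 1 and 0.43 without CPIP 2. The shares depend on the dissociation and are not tissue composition, and low-UMI clusters held 11.4% to 18.0% of the cells of a library.

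**Figure D1:**
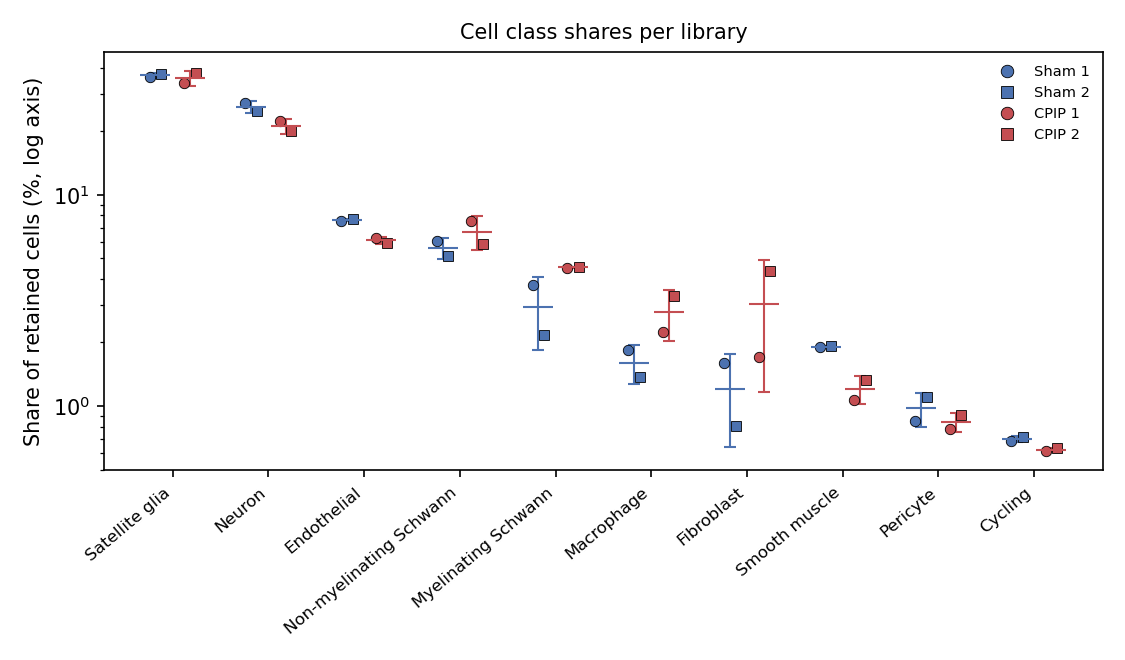
Share of retained cells (%, log axis) in each of 10 cell classes; each point is a library (circles replicate 1, squares replicate 2; Sham blue, CPIP red), and bars are the mean ± SD of 2 libraries. Both CPIP libraries lay below both Sham libraries for neurons (21.2% against 26.1% on average; not with low-UMI clusters joined to them) and above them for macrophages (2.79% against 1.61%).

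Within neurons, 3 clusters named as peptidergic nociceptors made up 26.2% ± 4.95 of neurons in Sham and 20.6% ± 0.921 in CPIP (SD, n = 2; exact permutation p = 0.33). The cluster led by Adcyap1, Npy1r and Calca showed no such difference, with 13.7%, 17.4%, 14.7% and 14.6% in Sham 1, Sham 2, CPIP 1 and CPIP 2. At this resolution the lower share came from a cluster led by Kcnv1, Nefm and Nefh (6.70%, 10.1%, 4.17% and 5.81%) and from a cluster of 175 cells led by none of the peptidergic markers. The former was named as large neurofilament at the finer resolution. The peptidergic share there was still lower in CPIP, with 14.26%, 17.09%, 12.7% and 11.91% in the same order. A cluster that scored highest for peptidergic markers but close to satellite glia was left unnamed there. It held 51, 62, 77 and 82 cells. Non-peptidergic nociceptor clusters made up 43.9% ± 4.09 and 40.8% ± 5.70 (exact p = 0.667). Clusters that scored highest for the marker list of Th-expressing low-threshold mechanoreceptors made up 7.43% ± 1.53 and 9.68% ± 0.258 (exact p = 0.33). Th itself was not among the leading genes of either. Of the 2 clusters so named, that led by Cbln2, S100b and Atp1b1 did not separate the groups (4.59%, 2.07%, 3.9% and 5.0%). Its leading genes included Ntrk2, a marker of the large neurofilament list, so its name is uncertain. A neuron cluster without a subtype, led by S100a16, Nrp2 and Sema5a, made up 4.35% ± 1.225 and 7.665% ± 1.176 (exact p = 0.33). The Trpm8 cluster, named for the cold receptor, made up 2.81% ± 0.138 and 4.09% ± 0.262 (exact p = 0.33). The Sst or Nppb cluster, named for a pair of itch-related neuropeptides, made up 6.02% ± 1.80 and 5.31% ± 0.464 (exact p = 1.0). Large neurofilament-rich neurons made up 4.30% ± 0.789 and 5.38% ± 1.82 (exact p = 0.667), a ratio that turned over at the finer sub-cluster resolution (−0.31 on the log2 scale). Among macrophages, the sub-clusters that kept the macrophage name held 19.3% ± 1.75 in Sham and 29.3% ± 4.47 in CPIP (exact p = 0.33). Markers were scored against the other sub-clusters of the class, so unnamed sub-clusters may hold macrophages too. At the finer resolution the share was 49.0% ± 9.33 in Sham and 59.3% ± 3.97 in CPIP. The sub-cluster led by Il1a, Il1b, Pf4 and Cd163 did not separate the groups, with 12.7%, 20.5%, 21.2% and 18.4%. The other was led by Pla2g2d and F13a1 and by no gene of the fixed macrophage marker list, though F13a1 is on the separate list of resident macrophage genes. It held 5.37%, 0%, 5.0% and 14.1% in Sham 1, Sham 2, CPIP 1 and CPIP 2. Sub-clusters led by genes of satellite glia (77 cells) and of neurons (61 cells) were also part of the macrophage class. None of these shares could pass the exact permutation test with 2 libraries per group.

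Rpl10a-ps9, annotated by its symbol as a processed copy of the ribosomal protein gene Rpl10a, was the only gene called between CPIP and Sham in any class, and it was higher in CPIP. In neurons it measured 0.772 ± 0.00715 CPM in Sham and 28.9 ± 9.20 CPM in CPIP (SD, n = 2; log2 fold change 5.22, SE 0.30, edgeR adjusted p = 0.0414). In endothelial cells the log2 fold change was 5.20 (SE 0.42, edgeR adjusted p = 0.00200) and in non-myelinating Schwann cells 4.26 (SE 0.52, edgeR adjusted p = 0.0458). Satellite glia gave 5.35 (SE 0.40, edgeR adjusted p = 0.314), and macrophages held 0 UMIs of it in both Sham libraries and 18 and 44 UMIs in CPIP 1 and CPIP 2. The neuronal call ended without Sham 1 (log2 fold change 5.23, edgeR adjusted p = 0.436) and without Sham 2 (5.21, 0.328), while the fold stayed close to 5.22. Because its UMIs and those of Rpl10a may have been divided by the counting, its level is uncertain.

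**Figure D2:**
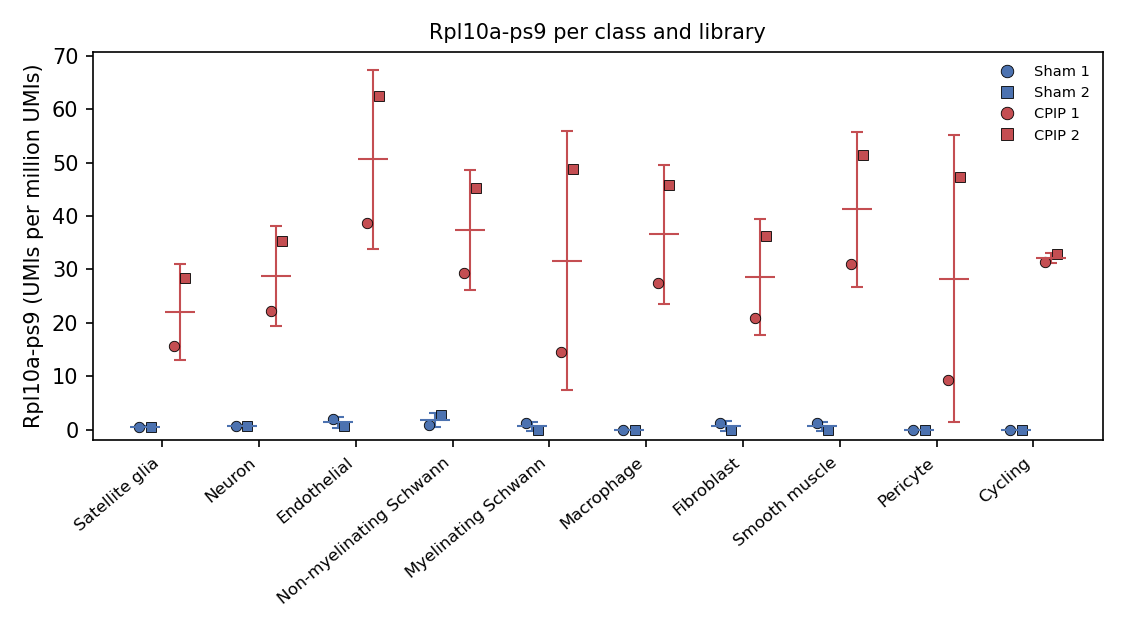
Rpl10a-ps9 in CPM of each cell class, without the TMM factor (linear axis); each point is a library (circles replicate 1, squares replicate 2; Sham blue, CPIP red), and bars are the mean ± SD of 2 libraries. In all 10 classes both CPIP libraries lay above both Sham libraries, for example 22.2 and 35.4 in neurons against 0.778 and 0.773.

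No other gene passed the test in the 6 classes with full accounts. The counts of called genes were 0 of 13013 tested in satellite glia, 1 of 13687 in neurons and 1 of 9936 in endothelial cells. They were 1 of 8236 in non-myelinating Schwann cells, 0 of 7286 in myelinating Schwann cells and 0 of 6525 in macrophages. With an unadjusted p under 0.05, edgeR gave 417, 410, 512, 409, 393 and 397 genes in that order, and DESeq2 called 7, 9, 1, 2, 1 and 2. The counts depended on single libraries. Without CPIP 1 they were 600, 622, 217, 171, 76 and 83, and without CPIP 2 they were 39, 47, 20, 19, 15 and 34. Without Sham 1 they were 0, 0, 63, 2, 0 and 36, and without Sham 2 they were 0, 0, 25, 2, 0 and 67. Fixed gene lists were compared as sets in these classes, and camera called 41 of the 156 tests, 28 higher and 13 lower in CPIP. None of the 41 calls held with an estimated correlation (adjusted p = 0.794 for each), and none held with fry (adjusted p of at least 0.460). With 2 libraries per group both tests had few degrees of freedom, and neither was checked on simulated counts. Here and below, a call lost under them cannot tell an absent change from low power, and the calls stay unsecured. The preset correlation of 0.01 treats the members of a list as nearly independent. A shift of a whole library moves members together, so the camera p may be far too small. It does not measure the spread between replicate libraries. In 32 of the 41 the mean log CPM of the list lay on the same side of both Sham libraries in both CPIP libraries, as the call has it, and in 9 the libraries overlapped. The lists were called on these same libraries, so this is no separate support. Some uncalled lists, such as axon injury genes in satellite glia, lay apart as well. Features with symbols that start like those of ribosomal protein genes were called higher by camera in all 6 classes, with medians of 0.06 to 0.15 (log2). The smallest adjusted p of this list with an estimated correlation was 0.157. The list held 167 features, among them copies such as Rpl10a-ps9.

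**Figure D3:**
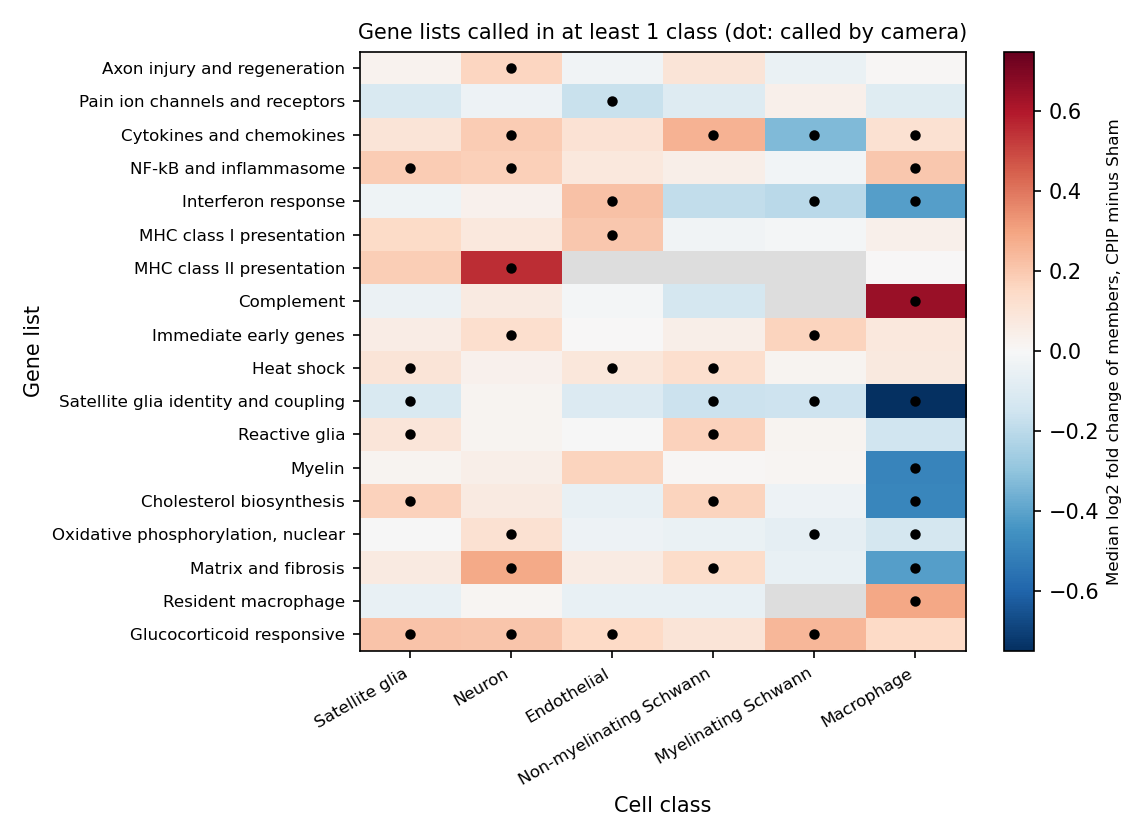
Median log2 fold change (CPIP minus Sham, colour) of the members of 18 gene lists called in at least 1 of 6 cell classes; dots mark lists called by camera at the preset correlation, and grey marks lists with fewer than 5 tested members. The medians ran from −0.75 for satellite glia genes in macrophages to 0.65 for complement genes in macrophages.

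In satellite glia camera called cholesterol biosynthesis genes higher in CPIP. All 25 tested members had positive log2 changes with a median of 0.17 (camera adjusted p = 4.8e-06; adjusted p = 0.794 with an estimated correlation). No member passed the test, over all genes or adjusted over the list alone. Msmo1, a sterol demethylase, measured 1179 ± 48.6 CPM in Sham and 1471 ± 133.8 in CPIP (SD, n = 2). NF-kB and inflammasome genes were called higher (15 of 19 positive, median 0.19, camera adjusted p = 8.0e-04), as were heat shock genes (18 of 21, median 0.10, 0.00948). So were reactive glia genes (12 of 18, median 0.09, 0.0183) and glucocorticoid-responsive genes (11 of 17, median 0.21, 0.00649). None held with an estimated correlation (adjusted p = 0.794), and of all these members only Sult1a1, from the glucocorticoid list, passed when adjusted over the list alone. Gfap, the glial filament protein, measured 20.2 ± 0.419 CPM in Sham and 27.1 ± 2.82 in CPIP; Stat3, a cytokine-activated transcription factor, measured 450.5 ± 12.1 and 583.0 ± 62.1. Satellite glia identity genes were called lower (5 of 22 positive, median −0.12, camera adjusted p = 0.00577; adjusted p = 0.794 with an estimated correlation), among them Slc1a3, a glutamate transporter, with 223.5 ± 3.90 and 187.7 ± 6.29 CPM.

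The genes with the smallest p in satellite glia after Rpl10a-ps9 were Capn6 (log2 fold change −1.06, SE 0.13), Tuft1 (1.06, SE 0.14), Rfxank (−0.62, SE 0.09) and Aldh2 (1.07, SE 0.18), none past the test (edgeR adjusted p = 0.971). The cholesterol call held with each library left out. Without CPIP 1 the calls of NF-kB (camera adjusted p = 0.203), heat shock (0.178) and reactive glia genes (0.118) ended. Without Sham 1 those of heat shock (0.424) and glucocorticoid-responsive genes (0.329) ended. Without Sham 2 those of identity (0.402) and reactive glia genes (0.0607) ended, and without CPIP 2 those of identity (0.0892) and glucocorticoid-responsive genes (0.163). Clusters led by inflammatory and immediate early genes such as Cxcl10, Ccl2, Gbp5 and Egr1 were part of this class. So was a cluster led by Cdh19, Prrg4 and Scn7a, the last 2 also leading genes of non-myelinating Schwann cells. It held 411, 485, 683 and 536 of the 4008, 4138, 3896 and 4441 satellite glia of Sham 1, Sham 2, CPIP 1 and CPIP 2, so the make-up of the class differed between libraries.

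In CPIP neurons the nuclear genes of oxidative phosphorylation were called higher, with 43 of 51 members positive and a median log2 change of 0.11 (camera adjusted p = 5.7e-06; adjusted p = 0.794 with an estimated correlation). The mean log2 CPM of the list was 7.84 in both Sham libraries, 7.83 in CPIP 1 and 7.98 in CPIP 2, so CPIP 1 was not above Sham. No member passed over all genes or adjusted over the list alone; Uqcr10, a subunit of complex III, measured 283.7 ± 26.9 CPM in Sham and 357.0 ± 14.5 in CPIP (SD, n = 2). Over the same libraries the 13 mitochondrially encoded genes were called lower (1 positive, median −0.16, camera adjusted p = 9.0e-08; adjusted p = 0.157 with an estimated correlation). Axon injury and regeneration genes were called higher (20 of 25 positive, median 0.16, camera adjusted p = 0.00164; adjusted p = 0.794 with an estimated correlation). Past the test adjusted over the list alone was 1 member, Sprr1a, a small proline-rich protein induced in injured neurons. Sprr1a had 0 UMIs in each Sham library, which allows up to 0.111 and 0.116 CPM, and 16 and 15 UMIs in CPIP 1 and CPIP 2. Vip, a neuropeptide, measured 0.745 ± 0.844 CPM in Sham and 7.54 ± 3.92 in CPIP, and Atf3, a stress-induced transcription factor, 47.9 ± 5.6 and 60.9 ± 5.04. Of the UMIs in CPIP 1 and CPIP 2 neurons, 18 and 14 cells of 1 sub-cluster held 233 of 251 and 106 of 110 for Vip and 16 of 16 and 13 of 15 for Sprr1a. They held a smaller part for Atf3 (110 of 1396 and 80 of 1488), Gal (60 of 232 and 164 of 657) and Flrt3 (89 of 1395 and 51 of 1182). Vip, Gal, Atf3, Flrt3, Hspb1 and Cacna2d1 are list members that lead this sub-cluster. Losing the call without its cells therefore cannot decide whether these cells carry it. The axon injury call ended without the 33 neurons of the sub-cluster led by Vip, Gal and Atf3 (camera adjusted p = 0.453, median 0.04) and without Sham 1 (0.0671).

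Further lists called higher in neurons were matrix and fibrosis genes (27 of 33 positive, median 0.29, camera adjusted p = 5.2e-05), glucocorticoid-responsive genes (14 of 14, median 0.21, 9.4e-04) and immediate early genes (29 of 35, median 0.13, 0.00119). Also called higher were cytokines and chemokines (17 of 21, median 0.19, 0.00326), NF-kB and inflammasome genes (14 of 18, median 0.18, 0.00948) and MHC class II genes (6 of 7, median 0.55, 0.0482). Each had an adjusted p of 0.794 with an estimated correlation. Adjusted over the list alone, Tgfbi of the matrix list and Ccl7 of the cytokine list passed. Ccl7, a chemokine, measured 16.9 ± 1.36 CPM in Sham and 30.1 ± 3.43 in CPIP (SD, n = 2). The matrix list moved with fibroblast markers, of which 8 of 9 were positive in neurons (median 0.26, camera adjusted p = 0.0248; adjusted p = 0.83 with an estimated correlation). Without Sham 1 the calls of matrix (camera adjusted p = 0.0760), glucocorticoid-responsive (0.0663), immediate early (0.841, with the direction turned), cytokine (0.254) and NF-kB genes (0.313) ended. Without CPIP 1 those of cytokine (0.0848), NF-kB (0.0661) and MHC class II genes (0.203) ended, and without Sham 2 that of MHC class II genes (0.476). Without CPIP 2 the calls ended for glucocorticoid-responsive (0.0580), immediate early (0.202), NF-kB (0.153) and MHC class II genes (0.459). The MHC class II call also ended without mixed sub-clusters (0.249). Among single genes, Tgfbi (log2 fold change 2.57, SE 0.23, edgeR adjusted p = 0.263), Nsg1, a neuronal endosomal protein (0.72, SE 0.08, 0.498), Crisp3 (1 UMI in Sham, 0.498) and Pimreg (−1.79, SE 0.25, 0.872) followed Rpl10a-ps9 and did not pass. The Vip sub-cluster held 74 of 97 Tgfbi UMIs of neurons in CPIP 1 and 73 of 100 in CPIP 2, and 32 of 32 and 30 of 33 for Crisp3.

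In endothelial cells camera called interferon-response genes higher in CPIP, with 26 of 31 members positive and a median log2 change of 0.22 (camera adjusted p = 1.5e-04; adjusted p = 0.794 with an estimated correlation). MHC class I genes (11 of 14, median 0.20, 0.0143), heat shock genes (17 of 20, median 0.08, 0.0111) and glucocorticoid-responsive genes (14 of 15, median 0.15, 0.00516) were also called higher. All 4 lists had an adjusted p of 0.794 with an estimated correlation and no member past the test, over all genes or adjusted over the list alone. Ifitm3, an antiviral membrane protein, measured 765.1 ± 6.66 CPM in Sham and 959.9 ± 40.7 in CPIP (SD, n = 2), and Tap1, the antigen peptide transporter, 64.2 ± 7.11 and 84.9 ± 3.20. Pain ion channel and receptor genes were called lower (6 of 22 positive, median −0.17, camera adjusted p = 0.0347; adjusted p = 0.794 with an estimated correlation; 1 member past adjusted over the list alone). Its leading members Scn11a and Scn10a, sodium channels of nociceptors, and P2rx3, an ATP receptor of nociceptors, are neuronal genes, and neuron markers were also lower in this class (5 of 17 positive, median −0.25, camera adjusted p = 0.00114). Fibroblast markers were higher (5 of 6, median 0.38, 0.0123); both marker lists had an adjusted p of 0.83 with an estimated correlation. Bmp4, a secreted growth factor (log2 fold change 2.30, SE 0.41), Calca, the CGRP gene (−0.72, SE 0.13), Scn11a (−0.97, SE 0.19) and Efemp1 (1.56, SE 0.30) had the smallest p after Rpl10a-ps9 and did not pass (edgeR adjusted p = 0.579). The interferon call ended without Sham 2 (camera adjusted p = 0.0930) and without CPIP 2 (0.550), the MHC class I call without CPIP 2 (0.113) and the heat shock call without CPIP 1 (0.226). The glucocorticoid call ended without Sham 1 (0.198) and CPIP 2 (0.0923) and the ion channel call without Sham 1 (0.0503), CPIP 1 (0.118) and CPIP 2 (0.227).

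In non-myelinating Schwann cells cholesterol biosynthesis genes were called higher in CPIP, with 19 of 21 members positive and a median of 0.17 (camera adjusted p = 4.8e-06, and 0.794 with an estimated correlation). The bounds of this class were loose. Fibroblasts were its next class by markers, with Col3a1 and Col6a3 among its leading genes. It held 673, 569, 873 and 682 cells in Sham 1, Sham 2, CPIP 1 and CPIP 2, but 481, 331, 575 and 492 with doublets kept. No member passed over all genes, and Idi1 and Tm7sf2 passed adjusted over the list alone. Idi1, an isoprenoid isomerase, measured 1168 ± 97.9 CPM in Sham and 1623 ± 20.4 in CPIP (SD, n = 2). Cytokine (8 of 9 positive, median 0.26, camera adjusted p = 0.00516), heat shock (16 of 20, median 0.13, 0.00280), reactive glia (12 of 16, median 0.18, 0.0114) and matrix genes (19 of 29, median 0.14, 0.0347) were called higher. Satellite glia identity genes were called lower (6 of 21, median −0.16, 0.0197). None held with an estimated correlation (adjusted p = 0.794). Adjusted over their lists alone, Lif, a cytokine of nerve injury (13.5 ± 4.31 and 28.7 ± 0.205 CPM), passed as higher and Cxcl10, an interferon-induced chemokine (1508 ± 113.6 and 1144 ± 125.0 CPM), as lower. The 13 mitochondrially encoded genes were lower (1 positive, median −0.12, camera adjusted p = 0.00106; adjusted p = 0.474 with an estimated correlation).

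Among the single genes with the smallest p in non-myelinating Schwann cells after Rpl10a-ps9 were Trib1 (log2 fold change 0.70, SE 0.11), Tnfrsf12a, the TWEAK receptor (0.90, SE 0.15), and Nr1d1, a repressor of the circadian clock (−2.44, SE 0.41), none past the test (edgeR adjusted p = 0.163). The cholesterol call held with each library left out. The other calls ended without Sham 1 for cytokine (camera adjusted p = 0.254) and heat shock genes (0.484), and without CPIP 1 for cytokine (0.457), heat shock (0.178) and matrix genes (0.203). They ended without Sham 2 for identity (0.229), reactive glia (0.389) and matrix genes (0.870), and without CPIP 2 for identity (0.152), reactive glia (0.327) and matrix genes (0.0586).

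In myelinating Schwann cells immediate early genes, which are induced within minutes of stimulation, were called higher in CPIP. Of the members 22 of 32 were positive, with a median of 0.16 (camera adjusted p = 1.3e-04, and 0.794 with an estimated correlation). An effect of the tissue dissociation on this or other lists was not tested. Nr4a3, the member that passed adjusted over the list alone, measured 334.5 ± 75.7 CPM in Sham and 539.8 ± 34.9 in CPIP (SD, n = 2). The immediate early call held with each library left out. Glucocorticoid-responsive genes were called higher (8 of 10, median 0.25, camera adjusted p = 0.0212). Cytokine (2 of 5 positive, median −0.33, 0.0463), interferon-response (5 of 14, median −0.20, 0.0347), satellite glia identity (3 of 19, median −0.16, 0.0212) and oxidative phosphorylation genes (14 of 47, median −0.07, 0.0395) were called lower. These lists had an adjusted p of 0.794 with an estimated correlation. Cxcl10, a member of the cytokine and the interferon list, passed adjusted over each list alone and measured 412.1 ± 31 and 244.2 ± 1.21 CPM. Markers of non-myelinating Schwann cells (2 of 10 positive, median −0.24, camera adjusted p = 0.00951) and the mitochondrially encoded genes (2 of 12, median −0.10, 6.0e-05) were lower as well; with an estimated correlation their adjusted p was 0.83 and 0.415.

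Single genes led by Rpl17, a ribosomal protein (log2 fold change 0.84, SE 0.12, edgeR adjusted p = 0.106), Cxcl10 (−0.76, SE 0.12, 0.171), Nr4a3 (0.67, SE 0.14, 0.886) and Ddx17, an RNA helicase (0.45, SE 0.10, 0.886), did not pass in myelinating Schwann cells. Of the 6 list calls of this class, that of glucocorticoid-responsive genes ended without Sham 1 (camera adjusted p = 0.801) and CPIP 2 (0.481). The cytokine call ended without Sham 1 (0.611) and CPIP 1 (0.421), with too few members tested without CPIP 2. The interferon call ended without Sham 1 (0.0709) and CPIP 1 (0.226), the identity call without Sham 1 (0.102), Sham 2 (0.12) and CPIP 1 (0.114), and the oxidative phosphorylation call without Sham 1 (0.0928), Sham 2 (0.294), CPIP 1 (0.190) and CPIP 2 (0.0923).

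In macrophages camera called complement genes higher in CPIP, with 14 of 16 members positive and a median log2 change of 0.65 (camera adjusted p = 3.6e-05; adjusted p = 0.794 with an estimated correlation). Resident macrophage genes were also called higher, with 10 of 14 positive and a median of 0.29 (9.4e-04; adjusted p = 0.794 with an estimated correlation). Both calls held with each library left out and without the sub-clusters led by genes of glia and neurons (0.00119 and 0.0111). Without those sub-clusters the complement median was 0.42, that of resident macrophage genes 0.21, and that of macrophage markers 0.18 against 0.34 with them. The make-up of the class differed between libraries, with the sub-cluster led by Pla2g2d and F13a1 at 5.37%, 0%, 5.0% and 14.1%. Its leading genes F13a1 and C6 are on the resident macrophage and the complement list, and the calls were not repeated without it. In addition, 3 sub-clusters of 299, 167 and 140 of the 1007 cells of the class were left unnamed. C1qc, a chain of complement component C1q, measured 982.5 ± 8.48 CPM in Sham and 1536 ± 315.5 in CPIP (SD, n = 2). Mrc1, the mannose receptor, measured 590.2 ± 83.5 and 850.0 ± 24.8 CPM, and Cd163, a haemoglobin scavenger receptor, 92.4 ± 10.9 and 214.3 ± 14.5. Cd163 was the member of these lists that passed adjusted over the list alone; relative to all other cells its log2 change turned to −1.15 (edgeR adjusted p = 0.993). Macrophage markers were higher (12 of 14, median 0.34, camera adjusted p = 6.0e-06), and markers of satellite glia (2 of 15 positive, median −0.64, 1.1e-07) and myelinating Schwann cells (1 of 7, median −0.44, 2.2e-04) were lower in the same libraries, each with an adjusted p of 0.83 with an estimated correlation. Cytokine (17 of 26, median 0.12, 0.0286) and NF-kB genes (14 of 19, median 0.20, 0.0183) were called higher with an adjusted p of 0.794 with an estimated correlation; Il1b, the interleukin-1 beta gene, measured 2323 ± 187.3 and 3373 ± 114.6 CPM.

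Lists called lower in macrophages were satellite glia identity (2 of 19 positive, median −0.75, camera adjusted p = 4.5e-11), myelin (2 of 12, median −0.50, 1.2e-05) and cholesterol biosynthesis (3 of 19, median −0.49, 3.7e-05). Also called lower were interferon-response (2 of 21, median −0.41, 0.00577), matrix (7 of 19, median −0.41, 0.0395) and oxidative phosphorylation genes (12 of 44, median −0.13, 0.0463). Each had an adjusted p of 0.794 with an estimated correlation. Adjusted over the list alone, 9 satellite glia identity and 2 myelin genes passed as lower and 1 matrix gene as higher. Fabp7, a fatty acid-binding protein of glia (log2 fold change −1.38, SE 0.21, edgeR adjusted p = 0.190), and Fbln2, a matrix protein (−1.16, SE 0.19, 0.190), were among the genes with the smallest p, with Gpnmb, a lysosomal glycoprotein (1.16, SE 0.20, 0.286), and Cd163 (1.23, SE 0.23, 0.315). Without the mixed sub-clusters the calls ended for satellite glia identity (camera adjusted p = 0.421), myelin (0.650), cholesterol (0.395, direction turned) and interferon genes (0.192). They also ended for oxidative phosphorylation (0.192), cytokine (0.915) and NF-kB genes (0.775), and the matrix list turned to higher (0.0226). Its median of 0.63 there went with medians of 0.63 for fibroblast markers and 0.51 for endothelial markers.

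Single libraries also ended macrophage list calls. Without Sham 1 these were the calls of NF-kB (camera adjusted p = 0.215), interferon (0.394, direction turned), myelin (0.0503), cholesterol (0.520), oxidative phosphorylation (0.681) and matrix genes (0.555, direction turned). Without Sham 2 they were those of cytokine (0.713, direction turned) and oxidative phosphorylation genes (0.0930). Without CPIP 1 the calls ended for NF-kB (0.248), interferon (0.216), oxidative phosphorylation (0.359) and matrix genes (0.742, direction turned), and without CPIP 2 for cytokine (0.355) and oxidative phosphorylation genes (0.0565).

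In fibroblasts, smooth muscle cells, pericytes and cycling cells edgeR called 0 of 7121, 5852, 2564 and 5766 tested genes, with 171, 310, 154 and 260 genes at an unadjusted p under 0.05, and DESeq2 called 0 in each. With 1 library left out, smooth muscle cells gave 17 genes without Sham 1, 79 without Sham 2, 57 without CPIP 1 and 11 without CPIP 2, pericytes 21, 1, 10 and 39, cycling cells 0, 0, 35 and 19, and fibroblasts 0 each time.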

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

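The lists, the set test with an estimated correlation and the fits with 1 library left out were fixed in advance; the other tests in this part were chosen after the values had been seen. Groups of 2 libraries were too small for a test of single outlying libraries.

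The list of cholesterol biosynthesis genes had changes of opposite sign in 2 pairs of classes, none of which held with an estimated correlation (adjusted p = 0.794): the mean log CPM of the list was 0.18 (log2) higher in CPIP in satellite glia and 0.36 lower in macrophages, a difference of 0.533 that was not tested. The change in non-myelinating Schwann cells was 0.22, which differs by 0.577 from the change of −0.36 in macrophages, also untested; the macrophage direction turned when the mixed sub-clusters were left out (median 0.15, camera adjusted p = 0.395). Interferon-response genes were 0.27 higher in endothelial cells and 0.22 lower in myelinating Schwann cells, an untested difference of 0.486. The list means were 6.05 and 5.92 in Sham against 6.08 and 6.43 in CPIP 1 and CPIP 2 in endothelial cells, where the call ended without CPIP 2 (camera adjusted p = 0.550), and 4.92 and 4.96 against 4.55 and 4.90 in myelinating Schwann cells, so single libraries carry much of both changes.

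Rpl10a-ps9 also appeared in the low-UMI clusters, with 1 UMI over both Sham libraries and 57 over both CPIP libraries, a ratio of CPM of 47.7 (95% counting interval 8.23 to 1920). This pattern, a higher level in CPIP in 12 groups of cells, was weighed against a response of particular cell classes and against UMIs of Rpl10a counted under its copy. A change limited to some classes is argued against among the 4 with more than 3 Sham UMIs (satellite glia, neurons, endothelial and non-myelinating Schwann cells), where the lower CPIP library had 10.9 to 28.5 times the CPM of the higher Sham library; the other 8 groups were higher too, but the lowest, pericytes with 0 Sham and 7 CPIP UMIs (at least 3.11-fold against a floor of 3 UMIs over the group; highest ratio 59.6, in smooth muscle cells), had too few UMIs to decide for them. Both CPIP libraries held less Rpl10a than both Sham libraries in 5 of 10 tested classes. CPIP 2, which held the most Rpl10a-ps9, had the least Rpl10a of all libraries in each tested class. In neurons Rpl10a measured 225.1 CPM in CPIP 2, while the 291.4 of CPIP 1 lay between the 287.0 of Sham 1 and the 312.9 of Sham 2. A transfer of UMIs from Rpl10a therefore cannot be told apart from an independent change. An inherited difference between the outbred rats of the pools, a difference in how the libraries were processed, and an effect of the model itself stay open and were not tested.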

How the results depend on the processing

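The crossed pairing, the class comparisons within a library, limma on log CPM, the removal of mixed sub-clusters or of the Vip sub-cluster, the joining of low-UMI clusters and the removal of the highest 5% of doublet scores in every library were chosen after the data had been seen. Of 516 values of named genes under the alternatives, 390 kept direction and side of the threshold and 108 passed the test only there. A further 11 no longer passed and 7 turned direction. Only Rpl10a-ps9 in neurons, endothelial and non-myelinating Schwann cells passed in the main test. For the other named values, keeping the side means that they still did not pass. All 11 losses fell on these calls of Rpl10a-ps9, which also did not pass where their direction turned. Of 312 values of called lists 146 kept both, 159 lost the call and 7 turned direction. The cause of these changes was not tested, except where fewer libraries or cells entered.

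Counts of called genes are given in the order satellite glia, neurons, endothelial cells, non-myelinating Schwann cells, myelinating Schwann cells and macrophages (main 0, 1, 1, 1, 0 and 0). RLE size factors and limma on log CPM left all 6 counts as they were. DESeq2 gave 7, 9, 1, 2, 1 and 2, and no low-count filter 1, 1, 1, 66, 40 and 55. With 1 library left out the counts ran from 0 to 600, 0 to 622, 20 to 217, 2 to 171, 0 to 76 and 34 to 83. The replicate block gave 0, 1, 2, 52, 2 and 6. The numbers were not taken to pair the libraries, since deviations of same-numbered libraries correlated at −0.13, −0.06, −0.28, −0.12, −0.09 and −0.25. Crossed pairing gave 1, 1, 9, 21, 31 and 133. Doublets kept gave 0 in neurons, 12 in non-myelinating Schwann cells and 2 in macrophages. The highest 5% of doublet scores removed gave 0 in non-myelinating Schwann cells, 1 in myelinating Schwann cells and 2 in macrophages. The strict cell filter gave 0 in endothelial and non-myelinating Schwann cells. Resolution 2.0 gave 0 in non-myelinating and 1 in myelinating Schwann cells. Equal cell numbers gave 0 in non-myelinating Schwann cells, and neurons without mixed sub-clusters gave 0. Relative to the other classes limma gave 0 in neurons, endothelial and non-myelinating Schwann cells. EdgeR relative to all other cells gave 3 in satellite glia (Thbs1, Shisa3 and Serping1), 0 in neurons, 1 in endothelial cells (H19) and 0 in non-myelinating Schwann cells. In those class comparisons the limma and the edgeR log2 values of Rpl10a-ps9 were 1.04 and 0.13 in satellite glia, 0.99 and −0.0606 in neurons, and 0.55 and −0.0036 in endothelial cells. They were −0.85 and −0.93 in non-myelinating Schwann cells, −1.03 and 0.14 in myelinating Schwann cells, and −0.70 and 7.88 in macrophages, which held 0 Sham UMIs of it. None passed (adjusted p of at least 0.703). Cd163 turned direction in macrophages with −1.15.

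Lists called (main 6, 8, 5, 6, 6 and 10) numbered 0 in all 6 classes with an estimated correlation and 0 with fry. With 1 library left out they ran from 3 to 9, 3 to 9, 3 to 7, 3 to 7, 2 to 4 and 4 to 10, and macrophages without mixed sub-clusters gave 4. The replicate block ended 4 of the 41 list calls. Lists that turned direction were immediate early genes in neurons without Sham 1 (camera adjusted p = 0.841; range with 1 library left out 4.6e-11 to 0.841) and several in macrophages. These were cytokines without Sham 2 (0.713; range 1.6e-05 to 0.713), interferon genes without Sham 1 (0.394; range 2.1e-09 to 0.394) and cholesterol genes without mixed sub-clusters (0.395). Matrix genes turned without Sham 1 (0.555), without CPIP 1 (0.742; range 1.3e-04 to 0.742) and without mixed sub-clusters (0.0226).

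On the log2 scale the endothelial share ratio of −0.32 became −0.27 with doublets kept, −0.27 with the highest 5% of doublet scores removed and −0.17 under the strict filter, under which that of non-myelinating Schwann cells went from 0.25 to 0.86. The ratio of myelinating Schwann cells ran from 0.28 to 1.06 with 1 library left out. The edgeR test of cell counts called no class (smallest p 0.0225 in smooth muscle cells, adjusted p = 0.287). At sub-cluster resolution 1.0 the ratio of large neurofilament neurons was −0.31 and that of macrophage-named sub-clusters 0.28. Summed UMIs of 376591 to 960376 per library in macrophages compare with 21627665 to 26489344 in satellite glia, and simulated 2-fold changes were recovered at 26.8% in macrophages and 63.8% in satellite glia; depth was not separated from the spread between libraries.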

Other observations

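The tests of the sub-cluster led by Vip, Gal and Atf3 were written down before their results were seen; its doublet score, the run with 50 genes left out, the comparison with 3 other sub-clusters, the tests of CPIP 2 and the choice of the genes named below came after.

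Nr1d1, the clock repressor also known as REV-ERB alpha, had lower levels in CPIP in several classes. In satellite glia it measured 24.4 and 19.5 CPM in Sham 1 and Sham 2 and 8.92 and 12.0 in CPIP 1 and CPIP 2 (log2 fold change −1.06, SE 0.20, edgeR adjusted p = 0.971). In endothelial cells the values were 49.8, 29.7, 15.5 and 24.5 CPM, and in fibroblasts 22.9, 23.8, 9.39 and 13.1 CPM. Neurons differed little, with 9.91, 9.12, 7.31 and 9.19 CPM, and the groups overlapped in myelinating Schwann cells (19.9, 5.85, 11.0 and 14.7) and smooth muscle cells (36.2, 19.2, 25.8 and 7.26). No class passed the test, and the list of circadian clock genes was called in none of the 6 classes. Rpl17 was higher in both CPIP libraries than in both Sham libraries in all 10 tested classes, for instance 217.6 and 284.3 against 502.9 and 390.7 CPM in satellite glia, and did not pass the test in any class. A neuron sub-cluster led by Crtac1, S100b and Hoxc11, with large-neuron markers, held 82, 53, 1 and 29 cells in Sham 1, Sham 2, CPIP 1 and CPIP 2, and the Pvalb sub-cluster, with a marker of proprioceptors, held 65, 50, 105 and 127.

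A sub-cluster of 33 neurons led by Vip, Gal, Tgfbi, Sema6a, Csrp3, Hspb1, Atf3, Flrt3, Cacna2d1 and Crisp3 held 0, 1, 18 and 14 cells in Sham 1, Sham 2, CPIP 1 and CPIP 2. Mixtures with another cell type were not excluded: the median doublet score of 0.082 was the highest of 16 neuron sub-clusters (others up to 0.0522). Scores were computed per library, and 18 of these cells came from CPIP 1, where the doublet caller was taken to have failed. The median over these 10 genes of their CPM over the highest CPM in any other class or sub-cluster was 3.11. Tgfbi and Atf3 were higher elsewhere, with ratios of 0.466 and 0.469. These genes were picked as high in the sub-cluster and cannot decide. With its 50 leading genes left out of the clustering, the cluster holding most of these cells took 42.4% of them (39.4% in the first run, with 81 genes left out, among them the axon injury and neuropeptide lists), and they made up 2.4% of that cluster. Of 3 other small neuron sub-clusters treated in the same way, 1 held together (91.8% of its cells, 83.0% of the cluster) and 2 did not, so whether these genes alone set the group cannot be told apart from the effect of leaving out leading genes. Without these cells the axon injury list was no longer called in CPIP neurons (camera adjusted p = 0.4531). That test removes cells chosen by genes which include members of the list, so it cannot decide whether these few cells are the source of the call.

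CPIP 2 stood apart from the other libraries: leaving out CPIP 1 raised the genes called in the 6 main classes to 989 in at least 1 class, 22 of them in all 6. B3galt4, a glycosyltransferase, was among these 22, with 207.0 CPM in satellite glia of CPIP 2 and 37.2 to 47.3 in the other libraries, but for Eef1a1, an elongation factor, CPIP 1 stood apart, the lowest in all 10 tested classes (2854 CPM in satellite glia against 4481 to 5183). A difference in depth was not settled. The 3707 median UMIs of CPIP 2 lie inside the range of the other libraries, but this median pools the barcodes of all classes. The 3531 of CPIP 1 is the lowest. Over genes called without CPIP 1, a choice that favours large CPIP 2 changes, CPIP 1 moved by 0.0109 of the CPIP 2 change (median over 6 classes). The ratio was −0.0559 in satellite glia, −0.026 in neurons, −0.00765 in endothelial cells and 0.0295 in myelinating Schwann cells. It was 0.099 in non-myelinating Schwann cells and 0.202 in macrophages. For these genes a graded response to the model is argued against in satellite glia, neurons, endothelial cells and myelinating Schwann cells only. A shift of a whole library remains consistent with the values, though they do not say which of the CPIP libraries shifted for a given gene: across genes, which are not independent replicates, the difference of CPIP 2 from CPIP 1 in neurons correlated with that in satellite glia at r = 0.808, against 0.445 for the Sham pair, and r was higher for the CPIP pair in all 45 pairs of classes (median 0.37 against 0.129). What shifted the library was not tested, and a response of the CPIP 2 rats alone, reaching all classes, stays open.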
